A study of Mus musculus with 4 samples.

How the data were processed

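Caecum RNA from 4 female BALB/c mice was measured on CombiMatrix oligonucleotide arrays. Per the labels, RNA was amplified, labelled with the dye Cy5 and hybridised in 1 colour, and each array is 1 sample. The design text names 2 animals per group, 3 months old, which received either Bifidobacterium bifidum PRL2010 or water by mouth in 5 consecutive daily administrations. Groups were taken from the inoculation label, which gives 2 control arrays and 2 PRL2010 arrays. Which slide each array came from, and the day of each hybridisation, are not given in the sources used here.

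The authors deposited 1 table of intensity values on a linear scale, from 0 to the scanner maximum of 65535, for 65562 spots. The sorted intensity values were identical in all 4 deposited columns, so the arrays had been quantile normalized against each other before deposit. Scanner, background correction and filters are not given in the sources used here. Of the spots, 65460 carried a mouse RefSeq transcript accession and 102 were control spots, 53 of them negative controls by name. Probes were 35 to 40 bases long.

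Accessions were named without their versions through the RefSeq gene table for mouse, which matched 21180 of 24565 accessions and 58018 of 65460 probes; the others kept their accession and are counted but not named in the text. No genome build was named by the authors, so no coordinates are given. Probe names end in S or in X with a number, and the meaning of this ending is not stated in the sources used here.

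Intensities were converted to log2. Each array held 11 values at 0, which have no log, and the 37 probes with a value of 0 on any array were left out. At first only the single values at 0 had been left out, which gave 22 called genes and 97 genes at least 2-fold apart. The rule was changed after these results were seen, since a value missing from 1 array moves the mean of a gene with several probes. The log2 values of all remaining probes of a gene were averaged, which gave 23069 genes and unmatched accessions with a median of 3 probes each. No further normalization was applied, and no probe was left out for being dim.

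Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend, two-sided), with Benjamini-Hochberg adjustment over all 23069 genes and a threshold of 0.05. The fit had 2 residual degrees of freedom per gene and a prior worth 5.47. An exact permutation test of 2 against 2 arrays cannot give a p below 0.333, so p-values rest on the spread shared across genes. Genes at least 2-fold apart whose groups' values did not overlap were also counted, beside the same count for the other 2 splits of the 4 arrays. A set of 38 gene lists with 1023 genes, of which 987 were measured, was tested with camera at its preset correlation of 0.01, and with camera at an estimated correlation and fry beside it. These tests, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took up to 12 genes per direction past the threshold without overlap, by size of change. Places left were filled by the genes of smallest unadjusted p among those at least 2-fold apart without overlap. From each list described it took up to 4 members of smallest p, and it took Actb and Gapdh as reference genes.

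A spot was taken as above background where it exceeded the 95th percentile of the negative control spots of its array. Where a probe was not above background on either array of its dimmer group, its fold is a bound. The bound sets the mean log2 value of the brighter group against the mean, per array, of the higher of that percentile and the probe's own value. Where the brighter group was at the scanner maximum the fold is also a bound. The number of arrays limits the precision of every value.

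The scripts were tested on simulated data with the levels of the 23069 genes and variances drawn from the fitted limma prior. They recovered 51 of 100 genes changed by a log2 value of 1 and 97 of 100 changed by 2. There were 9 false calls, and 0 calls where no gene was changed. The simulated noise was normal and independent between genes, so limma's assumptions held by construction. These counts therefore test the scripts and do not give the error rate on the real arrays. Alternatives covered normalization, centring, dim genes, the probes used per gene, values at 0, the variance prior, each probe alone, arrays left out and replicate numbers as a block. Probes were also dealt at random to genes 100 times. Shares carry Wilson intervals and means or medians over genes carry bootstrap intervals from 10000 draws, both at 95%, made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.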

Results

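Transcript levels were measured in the caecum of BALB/c mice that had received Bifidobacterium bifidum PRL2010, a gut bifidobacterium, or water. The comparison asks whether colonization by this strain changed the host's expression profile. There were 4 arrays, 2 from PRL2010 mice and 2 from control mice. The median intensity was 564.9 on every array, because the deposited values share 1 distribution. Negative control spots had median intensities of 532.2 and 557.1 on the control arrays and 535.1 and 585.4 on the PRL2010 arrays, about the level of the median mouse probe. Of the mouse probes, 2.54% and 1.69% lay above the 95th percentile of the negative controls on control replicates 1 and 2, and 3.44% and 1.93% on PRL2010 replicates 1 and 2.

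**Figure D1:**
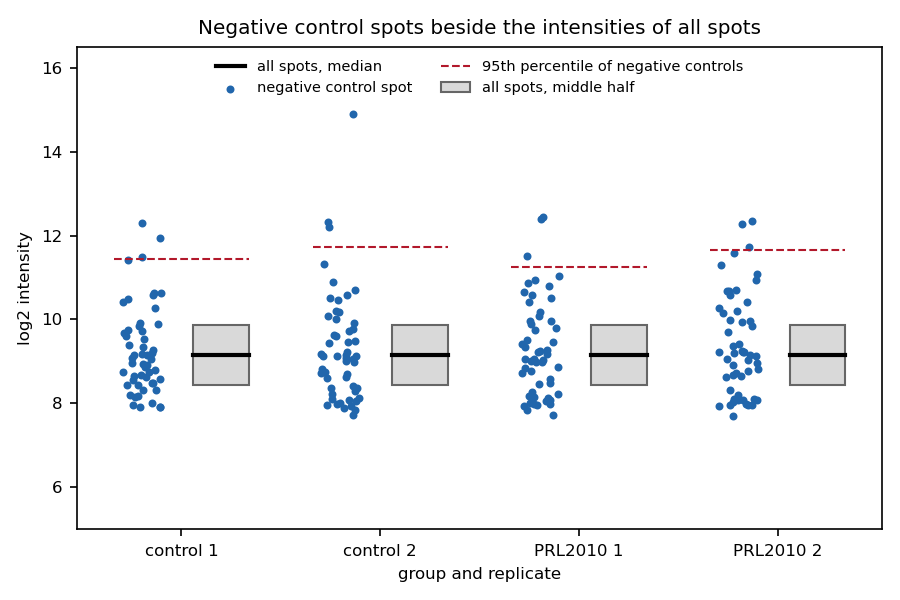
Log2 intensity (vertical axis) of the 53 negative control spots on each of the 4 arrays (points), beside the range of all spots between their lower and upper quartiles (grey box) and their median (black line). The red dashed line marks the 95th percentile of the negative controls, and the medians of all spots, at an intensity of 564.9, lie well below it on every array.

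In mice given PRL2010, 13 genes were higher and 8 were lower than in controls at an adjusted p under 0.05 in limma, and 9 of these 21 genes have a given name. By the mean of its probes Aldh1l1, a folate enzyme, rose by a log2 difference of 2.14 ± 0.14 (SE, n = 2 per group, limma adjusted p = 0.00721). Foxe3, a forkhead transcription factor of the lens, rose by 1.78 ± 0.15 and Dnajc9, a J-domain co-chaperone, by 1.67 ± 0.15. Defb18, a member of the beta-defensin family, was the only named gene that fell, with a log2 difference of -1.42 ± 0.16 (limma adjusted p = 0.0403).

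Other genes that rose were Atp1b1, a subunit of the sodium-potassium pump, by a log2 value of 1.59, Zfp397, a zinc finger gene, by 1.50, and Tspan7, a tetraspanin, by 1.41. Crmp1, a cytoskeletal regulator of neurons, rose by 1.28 and A2m, the protease inhibitor alpha-2-macroglobulin, by 1.27. Their limma adjusted p-values ran from 0.03 for Zfp397 to 0.0403 for A2m. The naming rule required groups without overlap, so each of these named genes but Defb18 was higher on both PRL2010 arrays than on both control arrays. Defb18 was lower on both.

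Most of these changes were read by a single probe. Of the 21 genes, 13 had only 1 probe, although 1756 genes on the array had 1 probe and 21314 had 2 or more. Genes with 1 probe were thus over-represented among the calls. The variance prior was shared by genes with 1 probe and with several, and whether this eased the calls of the former was not tested. Of the 8 with several, Dnajc9 alone had at least 2 probes that differed by 0.5 log2 or more in its direction. The leading probe of Aldh1l1 went from a mean intensity of 298.6 in controls to 36829 in PRL2010 mice, which is at least 11.9-fold higher, while its other 2 probes differed by -0.28 and -0.24 log2. For Crmp1 the leading probe was at least 16.3-fold higher and its other 4 probes lay between -0.50 and 0.46 log2. The leading probes of Tspan7, Dnajc9, A2m, Atp1b1 and Zfp397 were at least 7.62, 4.63, 4.41, 3.99 and 1.46-fold higher. Foxe3 was at least 2.38-fold higher by its single probe. Defb18, above background on all 4 arrays, was 2.67-fold lower by its single probe.

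**Figure D2:**
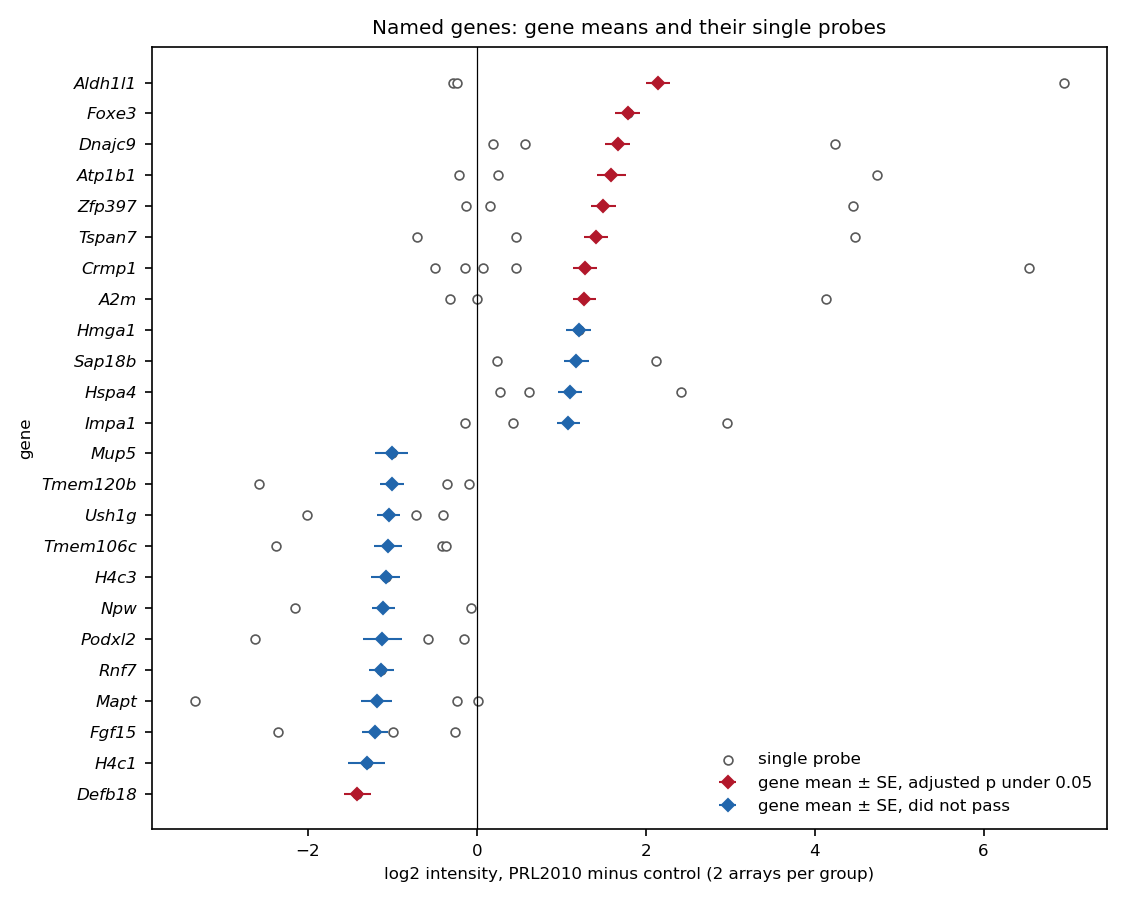
Log2 intensity difference, PRL2010 minus control (horizontal axis, 2 arrays per group), for each of 24 named genes (vertical axis). Diamonds are gene means with their limma SE, red where the adjusted p was under 0.05 and blue where it was not, and open circles are the single probes, drawn under the diamond where a gene has 1 probe. For Aldh1l1 1 probe lies at 6.95 and the other 2 lie at -0.28 and -0.24.

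Among genes at least 2-fold apart that did not pass the adjustment, Fgf15, a gut hormone that restrains bile acid synthesis in the liver, had a log2 difference of -1.20 ± 0.15 (limma adjusted p = 0.0612). All 3 of its probes were lower in PRL2010 mice, by -2.35, -0.999 and -0.26, and the first was above background on all 4 arrays. Hspa4, a chaperone of the heat shock family, was at 1.10 ± 0.14 (limma adjusted p = 0.0657), with all 3 probes higher. Agreement between probes adds no support for Fgf15 or Hspa4. Among genes at least 2-fold apart without overlap, 20 had 2 or more probes that differed by 0.5 log2 or more in the gene's direction. Dealing probes at random to genes gave a mean of 20.5 such genes. Hmga1, a chromatin protein, Sap18b and Impa1, an inositol monophosphatase, were at 1.20, 1.18 and 1.08. On the lower side Npw, which encodes neuropeptide W, was at -1.11, Rnf7, a ubiquitin ligase subunit, at -1.13 and Mapt, which encodes tau, at -1.19. The single probe of Rnf7 was at the scanner maximum on both control arrays, so the gene was at least 2.19-fold lower.

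Also named by the rule, and not past the adjustment, were Ush1g at -1.05, Tmem106c at -1.05, Tmem120b at -1.01 and Podxl2 at -1.12, each with all 3 of its probes lower in PRL2010 mice. As for Fgf15, this agreement between probes adds no support. Histone genes H4c1 and H4c3 were at -1.30 and -1.08, and Mup5, a major urinary protein gene, at -1.01, each by 1 probe. The probes of H4c1, H4c3, Mup5 and Hmga1 were above background on both arrays of neither group, so these values support no size of change.

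In all, 92 genes were at least 2-fold apart without overlap, 55 higher and 37 lower in PRL2010 mice. The other 2 splits of the arrays gave 22 and 24 such genes, and 0 and 0 genes past the limma threshold, with 385 and 450 genes at an unadjusted p under 0.05 against 2185 for the real split. The other splits mix both groups on each side, so any group difference widens their spread and lowers their counts. Those counts are therefore no measure of chance, and these 3 splits are too few for a share under 0.05. Groups did not overlap for 42.3% of all genes, where chance gives 33.3%. With the median of a gene's probes in place of their mean, 8 of the 9 named genes no longer passed, Aldh1l1 at 0.65 (limma adjusted p = 0.56) and A2m at 0.09 among them, and Foxe3 still did. Of these 8, Tspan7 at 1.29 and Defb18, unmoved at -1.42, lost little or none of their difference (limma adjusted p = 0.183 and 0.0934). Foxe3 and Defb18 were read by 1 probe each, so the median leaves their values as they were and does not test them. With an intensity trend in the limma prior only Aldh1l1 passed, and with an ordinary t statistic 0 genes did. Without control replicate 1 or 2 there were 693 and 4410 calls, and without PRL2010 replicate 1 or 2 there were 62 and 38.

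Of the reference genes, Actb had log2 levels of 12.68 and 11.20 on the control arrays and 12.48 and 11.88 on the PRL2010 arrays, a difference of 0.24 ± 0.43 (limma adjusted p = 0.874). With 1 array left out it ran from -0.49 without control replicate 2 to 0.98 without control replicate 1, where Actb passed (limma adjusted p = 0.00202). Gapdh differed by 0.48 ± 0.22 (limma adjusted p = 0.542). Across genes on the log2 scale, array pairs correlated at r = 0.951 within the PRL2010 group and 0.869 within the control group. Control replicate 2 and PRL2010 replicate 1 correlated at 0.928 on that scale. Across probes on the linear scale, where bright spots weigh most, r was 0.947 within the PRL2010 group and 0.907 within the control group. Between the groups it ran from 0.690 to 0.744. Genes are not independent replicates.

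Gene groups of the caecal wall were next compared as lists. Of their 987 genes, 61 had a probe above background on both arrays of a group, so most list values are differences between signals that were not above background. This holds on every array for each probe of Clca1, Agr2, Itln1, Rps4x, Slc26a3, Krt18, Cldn1, S100a9, Ccl4, Ccl7, Il13, Tgfb1, Nlrc4, Gip and Gapdh. Among mucus and goblet cell genes 8 of 23 members were lower and 2 higher on both PRL2010 arrays than on both control arrays. Over all genes, 42.3% did not overlap, in either direction. Counts without overlap, for this list and those below, were not tested against that share. Clca1, a secreted goblet cell protein, was at -0.96 ± 0.34, with all 3 probes lower by 0.5 log2 or more and none of them above background. Agreement of 2 or more probes adds no support. On the whole array 369 genes had 2 or more probes at least 0.5 log2 lower, against a mean of 363.8 with probes dealt at random. Agreement of all 3 probes was not counted apart. The log2 levels of the Clca1 probes were 11.003, 11.143 and 8.983 on control replicate 1. On control replicate 2 they were 9.6064, 10.011 and 7.9744. Both PRL2010 arrays were below control replicate 2 on each probe, but by less, so the size of the drop rests largely on control replicate 1. Fcgbp, a mucus protein, was at -0.67 ± 0.23 and Agr2, a mucin-folding protein of the endoplasmic reticulum, at -0.39 ± 0.14. The list had a median of -0.07 and did not pass (camera p = 0.0298, adjusted p = 0.502, and p = 0.387 before adjustment with an estimated correlation). Its mean was 0.20 log2 higher on control replicate 1 than on control replicate 2.

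None of the 38 lists passed camera, with 3 at an unadjusted p under 0.05. The smallest adjusted p was 0.502, against 0.916 with an estimated correlation and 0.593 by fry, where 0 and 2 lists had an unadjusted p under 0.05. No list member passed the limma threshold over all genes, and 11 members of 7 lists passed when adjusted over the list alone. List medians lay between -0.17 for pancreatic acinar genes and 0.17 for housekeeping genes, and 36 of 38 lay within 0.1 of 0. Of the pancreatic acinar genes, 10 of 20 were lower and 2 higher without overlap.

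**Figure D3:**
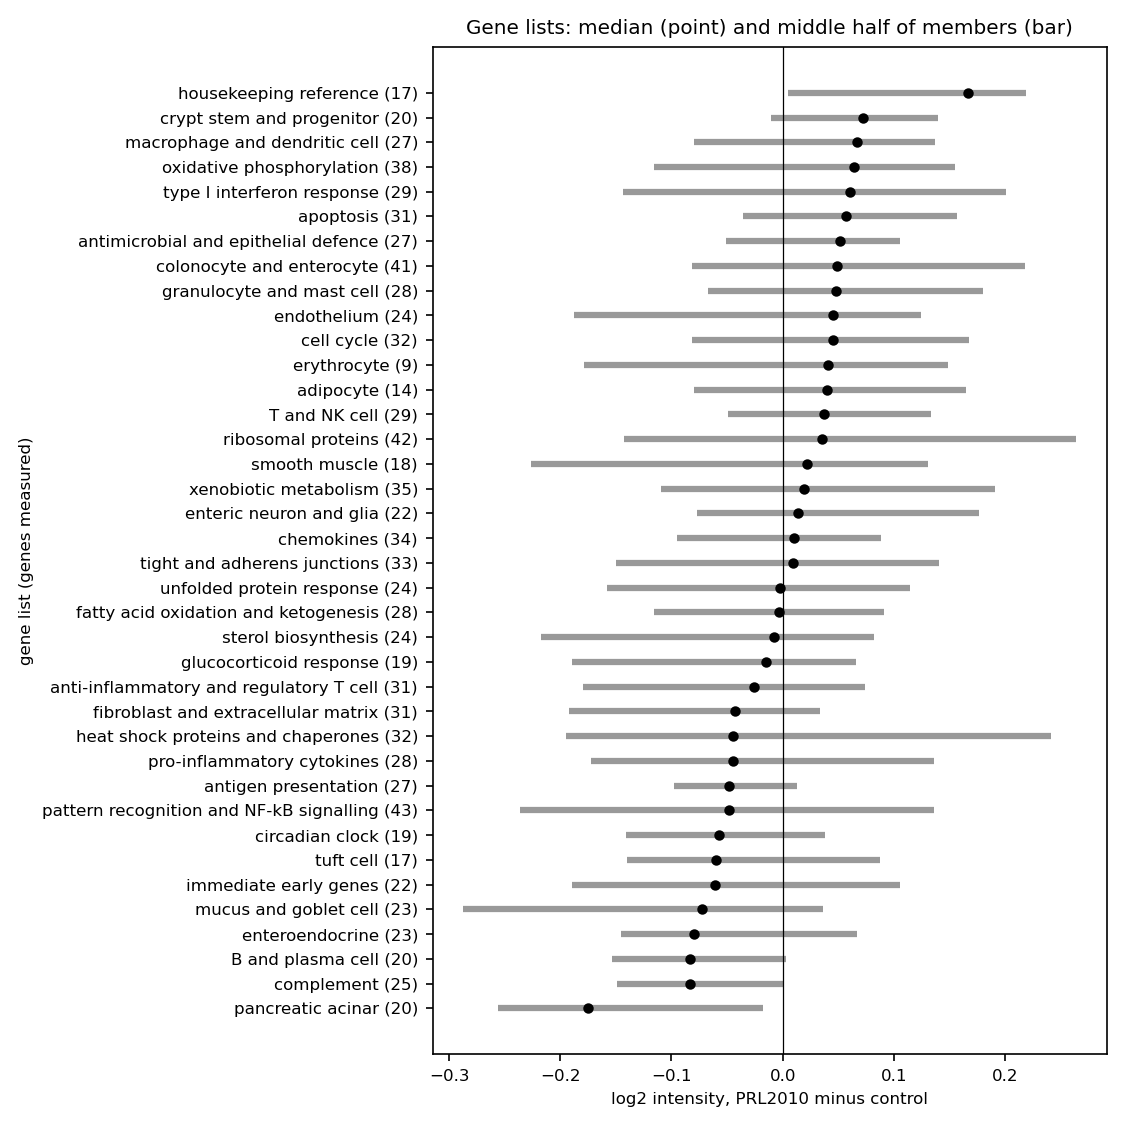
Median log2 intensity difference, PRL2010 minus control (points, horizontal axis), and the range between the lower and upper quartiles of the members (bars) for each of 38 gene lists (vertical axis, genes measured in brackets). The medians lie between -0.17 and 0.17, and no list passed the camera test.

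Complement genes, part of innate defence, had 10 of 25 members lower and 2 higher without overlap (median -0.08, camera p = 0.0355, adjusted p = 0.502, and p = 0.188 before adjustment with an estimated correlation). Serping1, the C1 inhibitor gene, at -0.67, and C3, the central complement component, at -0.69, passed limma when adjusted over the list alone, both at 0.0417, and did not pass over all genes. For Serping1 only 1 of 3 probes was lower. C3 was read by 1 probe, which was not above background on both arrays of either group. Housekeeping genes were the third list at an unadjusted p under 0.05 (median 0.17, camera p = 0.0465, p = 0.165 before adjustment with an estimated correlation).

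Heat shock proteins and chaperones went both ways, with 11 of 32 members higher and 11 lower without overlap. Their median was -0.04 and their mean 0.03 (camera adjusted p = 0.897). Hspa4 and Hspd1, the mitochondrial chaperonin, at 1.10 and 0.76, passed limma when adjusted over the list alone, at 0.00272 and 0.018. Hspb8, a small heat shock protein, was at -0.43 and did not. The value of Hspd1 rests on 1 probe at 2.02, with the others at -0.07 and 0.34. None of its probes was above background on both arrays of a group.

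Among ribosomal protein genes 13 of 42 members were higher and 6 lower without overlap. Their median was 0.04 (camera adjusted p = 0.502). Rpl32 at 0.89 and Rps4x at 0.70 passed limma when adjusted over the list alone, both at 0.0275, with both probes of Rpl32 and all 3 of Rps4x higher. As for Hspa4, this agreement between probes adds no support. Colonocyte and enterocyte genes had a median of 0.05 (camera adjusted p = 0.647), with the chloride exchanger Slc26a3 at 0.40 and the keratin Krt18 at 0.56, or -0.06 by its brightest probe. Without control replicate 1 the colonocyte and ribosomal lists passed camera upwards, at adjusted p = 0.00186 and 0.036, but not with an estimated correlation (p = 0.166 and 0.169 before adjustment, adjusted p = 0.993 for both). The colonocyte list had its own mean 0.20 higher on control replicate 1 than on control replicate 2.

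Barrier and defence genes stayed near 0 as lists. Tight and adherens junction genes had a median of 0.01 (camera adjusted p = 0.914), with 8 of 33 members higher and 7 lower without overlap. The claudin Cldn1 was at -0.41 ± 0.14 and passed neither over all genes nor over the list alone, at 0.459 and 0.61. Antimicrobial and epithelial defence genes had a median of 0.05 (camera adjusted p = 0.782). Within them Itln1, an intestinal lectin, was at -0.87 ± 0.21 with all 3 probes lower (limma adjusted p = 0.286). As for Clca1, this agreement between probes adds no support. The lectin Reg3g was at 0.37 and the neutrophil protein gene S100a9 at 0.55.

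Immune signalling lists did not pass either. Chemokines had a median of 0.01 (camera adjusted p = 0.914), with Ccl4 at 0.47, Cxcl9 at 0.61 and Ccl7 at -0.39. Pro-inflammatory cytokines had a median of -0.04 (camera adjusted p = 0.907), with 5 of 28 members higher and 8 lower without overlap and Il1b at -0.23. Anti-inflammatory and regulatory T cell genes had a median of -0.03 (camera adjusted p = 0.747), with Il13 at 0.57 and Tgfb1 at -0.39. Pattern recognition and NF-kB signalling genes had a median of -0.05 (camera adjusted p = 0.747), with the inflammasome gene Nlrc4 at -0.45 and Nfkb1 at 0.50 by 1 of its 3 probes, or -0.01 with their median. The type I interferon list had a median of 0.06 (camera adjusted p = 0.907).

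The other members that passed limma when adjusted over the list alone came from 3 lists of cell type markers and the cell cycle list. In the enteroendocrine list these were Gip, an incretin hormone gene, at 0.71 and Pax4 at 0.62, with values of 0.0222 and 0.0265. Others were Epor, the erythropoietin receptor gene, at 0.78 (0.0106), Mcm7, a replication helicase subunit, at 0.96 (0.0257) and Cpb1, a pancreatic carboxypeptidase, at 1.14 (0.00191). Only 1 probe differed by 0.5 log2 or more in the gene's direction for each of Gip, Pax4, Epor, Mcm7 and Cpb1. With the median of its probes Mcm7 was at -0.04. The enteroendocrine, erythrocyte, cell cycle and pancreatic acinar lists had medians of -0.08, 0.04, 0.05 and -0.17 (camera adjusted p = 0.914, 0.747, 0.747 and 0.502).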

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

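All tests of explanations here were chosen after the results were seen, and the demand below for other probes above the negative controls was added to the first of them after its result. Among the 102 control spots, whose group differences are not used above, 1 negative control spot named for a phage sequence was higher on both PRL2010 arrays than on both control arrays, by 1.17 log2. At 1.5-fold without overlap there were 8 control spots, 7 of them higher in the PRL2010 group, which is 7.84% (Wilson interval 4.03 to 14.7), beside 9.21% of mouse probes.

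The first pattern was that of the 8 called genes with several probes, 7 rest on 1 probe, Aldh1l1 and Crmp1 among them, while Dnajc9 had a second probe at 0.57 log2. The 17 other probes of the 8 genes had a median of 0.0043 log2 in the called direction (bootstrap interval -0.24 to 0.25), beside 4.47 for the leading probes. As a set, these other probes did not show the change that the leading probes showed. The demand for other probes above the negative controls on all arrays, which 0 of the 17 met, does not settle why. The leading probes of Aldh1l1, Crmp1, A2m, Tspan7, Atp1b1, Dnajc9 and Zfp397 did not meet it either. A change that other probes could also read and one that only the leading probe reads therefore both stay open. Differences of single spots that need no mouse transcript stay open too: 0.98% of the control spots were at least 2-fold apart without overlap (Wilson interval 0.173 to 5.35), beside 1.93% of mouse probes. The slide of each array is not given in the sources used here, and no test of it was run.

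A second pattern was a lower mean of mucus and goblet cell genes, such as Clca1 and Fcgbp, on the PRL2010 arrays, in a list that did not pass (camera adjusted p = 0.502). The list's mean was -0.26 log2 against control replicate 1 (bootstrap interval -0.44 to -0.09) and -0.0537 against control replicate 2 (-0.13 to 0.02). Lower goblet cell transcripts than in both controls therefore stay open. A stronger signal of epithelial transcripts in general on control replicate 1 was also considered. Colonocyte and enterocyte genes were 0.20 log2 higher there than on control replicate 2 (0.04 to 0.37). Their mean there, 9.653, was however level with 9.64 and 9.649 on PRL2010 replicates 1 and 2, and control replicate 2 was the low array at 9.45. That list thus shows no excess of control replicate 1 over the PRL2010 arrays.

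The third pattern was that the colonocyte and ribosomal lists passed without control replicate 1. Over their 83 genes, PRL2010 mice differed from control replicate 1 by 0.0224 log2 (bootstrap interval -0.07 to 0.12) and from control replicate 2 by 0.17 (0.10 to 0.25), so higher transcripts than in both controls stay open. With an estimated correlation neither list passed (camera adjusted p = 0.993 for both), so the pattern rests on the preset one. Weaker signal of abundant transcripts on control replicate 2 stays open as well. Over 45 abundant genes of no list that array differed from the others by a median of 0.0187 (-0.06 to 0.13), but the shared distribution holds such a value near 0. Of 5 genes with 3 probes all in the top 5% by level, Actb was lower there than on control replicate 1 by 1.47, Ece1 by 0.10, and 3 were higher by 0.42 to 0.48. Dealing probes at random to genes gave a mean of 2.16 such genes, from 0 to 7, so these 5 need not all be abundant transcripts.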

How the results depend on the processing

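The alternatives by median of probes, probe ending, values at 0, probe agreement and an estimated correlation with 1 array left out were chosen after the data were seen. Quantile normalization and centring moved little, since the deposited values already share 1 distribution. The 21 called genes became 288 with the brightest probe per gene, 11 with the median of probes (7 of them shared, Foxe3 the only one with a given name), 6 with probes ending in S, 1 with an intensity trend, 0 with an ordinary t statistic, 77 probes with each probe alone and 1 where at least 2 probes had to agree. They ranged from 38 to 4410 with 1 array left out, where the lone array of a group is assumed to vary like the other group. The 92 genes at least 2-fold apart became 856 with the brightest probe, 144 with the median of probes, 1261 with each probe alone, 20 at 3-fold and 20 where at least 2 probes had to agree, and ranged from 107 to 317 with 1 array left out. The count of lists that passed ranged from 0 to 2 with 1 array left out, the 2 being those without control replicate 1 at the preset correlation, and was 0 under every other alternative run. With the replicate block, 129 genes passed, the 21 among them, and 0 lists. Same-numbered deviations correlated at 0.0018 across genes. This gave no sign that the numbers pair the samples, but with most probes not above background it cannot exclude pairing. Genes with a given name past the threshold kept their direction wherever tested. With 1 array left out this was fixed in advance, since the naming rule required groups without overlap. Changes of the variance prior leave the log2 difference as it is. Foxe3 and Defb18 have 1 probe each, so the choice of probes cannot turn their direction either. Actb, Car1 and Krt20 ranged from -0.4947 to 0.9755, -0.2014 to 0.831 and -0.08263 to 0.1932 log2 with 1 array left out, and Actb and Car1 passed without control replicate 1 (limma adjusted p = 0.00202 and 0.00334). Krt18 turned to -0.062 with the brightest probe, Nfkb1 and Mcm7 to -0.007421 and -0.03848 with the median of probes, and Lypd8 and Car1 to -0.0544 and -0.0008698 with probes ending in S. The cause of these moves was not tested, apart from those built from fewer arrays, single probes or a stricter threshold. Signal over background also limits the values, as at most 3.44% of mouse probes lay above the negative controls' 95th percentile.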

Other observations

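All tests here were chosen after the data were seen, and so were the genes named. Several epithelial transcripts differed more between the 2 control arrays than between the groups. This is not particular to them. Across all genes the SD of the log2 differences was 0.340 between the 2 control arrays and 0.258 between the group means. Lypd8, which keeps flagellated bacteria off the colonic epithelium, had log2 levels of 11.22 and 9.80 on the control arrays and 11.29 and 11.26 on the PRL2010 arrays, and its difference of 0.76 did not pass (limma adjusted p = 0.577). Car1, a carbonic anhydrase of the colon, was at 11.39 and 10.36 in controls and 11.38 and 10.99 in PRL2010 mice. Krt20, an epithelial keratin, was at 10.75 and 10.48 in controls and 10.76 and 10.59 in PRL2010 mice. Lypd8, Car1 and Krt20 were each lower on control replicate 2 than on the other 3 arrays, and without it Car1 and Krt20 were at -0.20 and -0.08. Without control replicate 1 they were at 0.83 and 0.19, and Car1 passed (limma adjusted p = 0.00334). No probe of Krt20 was above background on any array.

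Of the 92 genes at least 2-fold apart without overlap, 20 had at least 2 probes that differed by 0.5 log2 or more in the gene's direction. They included Dnajc9, Fgf15 and Hspa4, and also Stat3, a transcription factor of cytokine signalling, with all 3 probes lower and a difference of -1.19 (limma adjusted p = 0.256). Dealing the probes at random to genes 100 times gave a mean of 20.5 such genes, from 12 to 32, out of a mean of 84.9 genes at least 2-fold apart.

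Over 59794 pairs of probes for 1 transcript, levels correlated at r = 0.0154 and PRL2010 minus control differences at 5.17e-05. Of 2291 other probes of a transcript with a probe at least 2-fold apart without overlap, 48.6% moved the same way (Wilson interval 46.6 to 50.7). Where the other probe lay above the negative controls on all arrays, it was 14 of 25, or 56.0% (37.1 to 73.3).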
